A study of Homo sapiens with 12 samples.

How the data were processed

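RNA sequencing measured gene expression in 12 libraries of Jurkat cells, an established line of T-cell acute lymphoblastic leukaemia. Per the labels, cells were treated with 1 µM brequinar (BRQ) or with DMSO for 8 h or 24 h, in triplicate, and total RNA was isolated with an RNeasy-Plus kit before library preparation and sequencing on an Illumina instrument at a service company. The submitters' processing notes name FastQC 0.11.9, MultiQC, STAR, featureCounts 1.6.3 from Subread 2.0.0, DESeq2 and the genome build hg19. Which step each tool was used for, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. The deposited table of counts holds whole numbers for 57820 gene identifiers in each library. The deposited log2(TPM+1) table holds TPM values on a log2 scale, as its values show, since the transformed values sum to between 999999 and 1000002 per library. How the gene lengths behind the TPM values were taken is not given in the sources used here.

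Each of the 12 columns was assigned to its group by the label of its sample, which gave 4 groups of 3. Gene symbols were those of the deposited tables. Of the identifiers, 52338 were found in GENCODE v29, which served for gene type, transcript GC content, transcript length and gene span. Its coordinates were not used, since its build differs from that of the deposited tables. In a check across genes, the length implied by count and TPM together had a Spearman correlation of 0.016 with the gene's own length over 10888 genes. The correlation was 0.935 over 9959 genes when the lengths in table order were given to the names in alphabetical order. TPM levels were therefore not compared between genes. Folds of log2(TPM+1) values, used in 1 alternative, are shrunk at low TPM by the added 1, and so depend on the length given to the gene.

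Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr on the groups, which left 11671 genes, and libraries were scaled by TMM (factors 0.8785 to 1.159). A quasi-likelihood model with robust dispersion and 1 coefficient per group was fitted to all 12 libraries, which share 1 estimate of the spread (biological coefficient of variation 0.16). The contrasts were BRQ against DMSO at 8 h, BRQ against DMSO at 24 h, the difference between these effects (an interaction term), and DMSO at 24 h against DMSO at 8 h. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors belong to the log2 fold changes of this model, and CPM (counts scaled to library size) use TMM and given as mean ± SD of 3 libraries. All tests were two-sided.

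For the gene lists, 31 pathway lists and 7 marker lists of other cell types were fixed, with the design and the alternative settings, before the data were examined. Of their 865 entries, 864 were matched, 4 of them by an older symbol. Pathway lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists. Tests with an estimated correlation and with fry were run beside it. The sign of a list's median differed from camera's direction in 5 lists at 8 h, 3 at 24 h, 2 for the difference and 3 for DMSO over time, and none of these lists was called. The 7 marker lists were given as summed CPM: B cell, myeloid, erythroid, megakaryocyte, NK cell, fibroblast and epithelial.

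The genes named in the text follow a rule fixed beforehand: the 8 largest rises and 8 largest falls of each BRQ comparison (6 and 6 for the other contrasts) among called genes with a mean log2 CPM of at least 1 and no overlap between the groups' libraries, up to 2 rising and 2 falling members of each list with the lowest adjusted p, and DHODH, UMPS, CAD, MYC and CDKN1A. Members of a list may be named where the list is described. Members of a list whose call was lost on leaving out 1 library were not taken as examples, a choice made after their values had been seen. Values of some members of lists are not reported here. Absence of overlap was not asked for the difference between times. Clone names, antisense genes and pseudogenes were skipped. An error in applying the skip, which had left out genes without a GENCODE v29 type, was corrected after values had been seen; it added MARCKS at 8 h and put CRIPAK in the place of TTC23 at 24 h and of JAG1 for the difference.

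Alternatives fixed beforehand were other scalings (median of ratios, upper quartile, library size only), DESeq2 1.42.0, other filters, a stricter threshold, a fold-change minimum, a fit of the compared groups alone, the replicate number as a block, limma-trend on the deposited log2(TPM+1) values, and leaving out each library in turn. Added after seeing the data were a GC correction, limma voom with sample weights, fits without libraries that stood apart or held markers of other cells, single DMSO 24 h libraries as the control, and a list of 39 splicing regulators. The procedure was tested on simulated counts for 11671 genes: in the comparison at 8 h it recovered 23.9% of genes changed by 1.5-fold, 61.2% of those changed by 2-fold and 84.8% of those changed by 4-fold, and 9 of 122 calls were false. For 24 h it recovered 10.4%, 50.7% and 92.4%, and 8 of 110 calls were false. The simulated groups had the same dispersion for a gene, and few genes were changed. In the data the biological coefficient of variation was 0.089 in the 8 h libraries alone and 0.213 in those of 24 h. The simulation therefore does not give the share of false calls or the recovery for the real groups. Where a group had 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group; where it had 1 to 3 counts, the ratio carries a 95% interval. Such floors and intervals cover counting error only. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for annotation, checks and plots.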

Results

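Jurkat cells were profiled after 8 h and 24 h with 1 µM brequinar or with DMSO. Brequinar inhibits DHODH, the mitochondrial enzyme that makes orotate in de novo pyrimidine synthesis. The 12 libraries form 4 groups of 3. Total counts per library were 3239844 to 3335770 in DMSO at 8 h and 3540003 to 4078893 in BRQ at 8 h. At 24 h they were 2951278 to 3523731 in DMSO and 4840071 to 5396130 in BRQ. The labels number the replicates but do not say that they were separate cultures, so they may be technical. Log2 fold changes are given with their standard error and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11671 genes.

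The comparison at 8 h asks what brequinar changes early. Of the tested genes 4 fell, and in each the 3 BRQ libraries lay below the 3 DMSO libraries. EIF4A2 (ENSG00000156976.10), a paralogue of the translation initiation helicase eIF4A1, fell by 0.89 ± 0.12 on the log2 scale, from 872 ± 44.7 to 470 ± 38.2 CPM (SD, n = 3; adjusted p = 0.00305). INTS6 (ENSG00000102786.10), a subunit of the Integrator complex that processes small nuclear RNA, fell by 0.99 ± 0.14, from 137 ± 14.2 to 68.9 ± 1.44 CPM (adjusted p = 0.00364). MARCKS (ENSG00000155130.5), an actin-binding substrate of protein kinase C, fell by 0.84 ± 0.12 (adjusted p = 0.00364), and EXT1 (ENSG00000182197.6), a polymerase of heparan sulphate, fell by 0.89 ± 0.14 (adjusted p = 0.0169). Each of the 4 calls was lost on leaving out single libraries, while the log2 fold changes kept their direction. Without BRQ 8 h replicate 1 or 3, all 4 were lost, at -0.848 and -0.888 for EIF4A2, -0.981 and -0.991 for INTS6, -0.851 and -0.852 for MARCKS, and -0.931 and -0.842 for EXT1. Without BRQ 8 h replicate 2, INTS6 (-1.004), MARCKS (-0.84) and EXT1 (-0.903) were lost. Without DMSO 8 h replicate 1 or 2, INTS6 (-0.943 and -0.945) and EXT1 (-0.938 and -0.75) were lost. In a fit of the 8 h libraries alone, which had a smaller spread, all 4 genes were called. Their edgeR adjusted p-values there ran from 3.33e-11 for EIF4A2 to 1.43e-05 for EXT1. The genes of de novo pyrimidine synthesis were not called: the log2 fold change was -0.08 ± 0.21 for DHODH and 0.09 ± 0.13 for UMPS, and CAD was at 263 ± 11.5 CPM with BRQ against 263 ± 26.1 CPM with DMSO. MYC was at 487 ± 11.1 CPM with BRQ against 481 ± 42.4 CPM with DMSO and was not called. CAD and MYC differed so little that leaving out single libraries changed the sign of their log2 fold change.

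**Figure D1:**
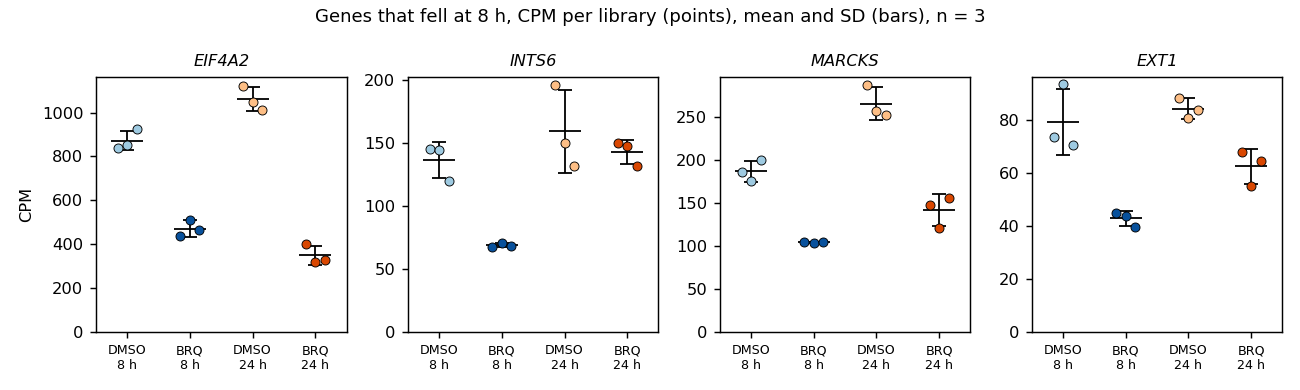
CPM (linear axes from 0) of the 4 genes that fell at 8 h, in each of the 12 libraries (points), with the group mean and SD (bars, n = 3). EIF4A2 averaged 872 CPM with DMSO and 470 CPM with BRQ at 8 h.

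Of the 31 gene lists, camera called cytosolic ribosomal proteins up at 8 h (76 genes tested, median log2 fold change 0.0869, adjusted p = 0.0396), with each member short of the gene-level threshold. The call was lost at adjusted p = 0.993 with an estimated correlation. That call was also lost without DMSO replicate 1 (adjusted p = 0.134), DMSO replicate 2 (0.924), BRQ replicate 2 (0.422) or BRQ replicate 3 (0.282) of 8 h, without DMSO 24 h replicate 3 (0.0744) and after GC correction (0.0665). In a fit of the 8 h libraries alone, camera called this list (adjusted p = 7.75e-06) and nuclear OXPHOS (0.00578) up. Both calls were lost there with an estimated correlation (adjusted p = 0.997 for each). For single genes, edgeR called 4 falls and 0 rises; 467 genes had an unadjusted p under 0.05 against 584 expected by chance, and DESeq2 called 36 falls and 1 rise. The groups' libraries did not overlap in 14.3% of genes, against 10% by chance. The edgeR count became 0 without BRQ 8 h replicate 1 or 3 (410 and 294 genes at an unadjusted p under 0.05), 1 without BRQ 8 h replicate 2, 2 without DMSO 8 h replicate 1 or 2, 8 without BRQ 24 h replicate 3 and 77 without DMSO 24 h replicate 1. A fit of the 6 libraries of 8 h alone called 185 genes, 6 rises and 179 falls, which include the 4 genes above. In that fit 1114 genes had an unadjusted p under 0.05, against 467 in the fit of all 12. The biological coefficient of variation of the 8 h libraries alone was 0.089, below the 0.16 of the fit of all 12. The number at an unadjusted p under 0.05 thus depends on which libraries share the estimate of the spread.

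The comparison at 24 h asks for the late response. MYC (ENSG00000136997.10), a transcription factor that drives growth, fell by 1.87 ± 0.12 on the log2 scale, from 401 ± 23.2 to 110 ± 14.2 CPM (n = 3; adjusted p = 4.95e-09). Of 39 tested genes of ribosome biogenesis, 27 fell, among them the assembly factor MRTO4 from 360 ± 7.71 to 140 ± 12.2 CPM. HSPA5, the main chaperone of the endoplasmic reticulum, fell from 975 ± 78.5 to 329 ± 35.6 CPM. RRM2, the small subunit of ribonucleotide reductase, rose from 371 ± 23.9 to 856 ± 135 CPM, and ISG15, an interferon-induced ubiquitin-like protein, rose from 40 ± 8.6 to 97.2 ± 19.4 CPM. DHODH (log2 fold change -0.27 ± 0.22), UMPS (-0.16 ± 0.13) and CAD (-0.18 ± 0.13) were not called (adjusted p = 0.37, 0.356 and 0.326), and all 3 values changed sign with library size as the only scaling (0.0175, 0.123 and 0.122).

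**Figure D2:**
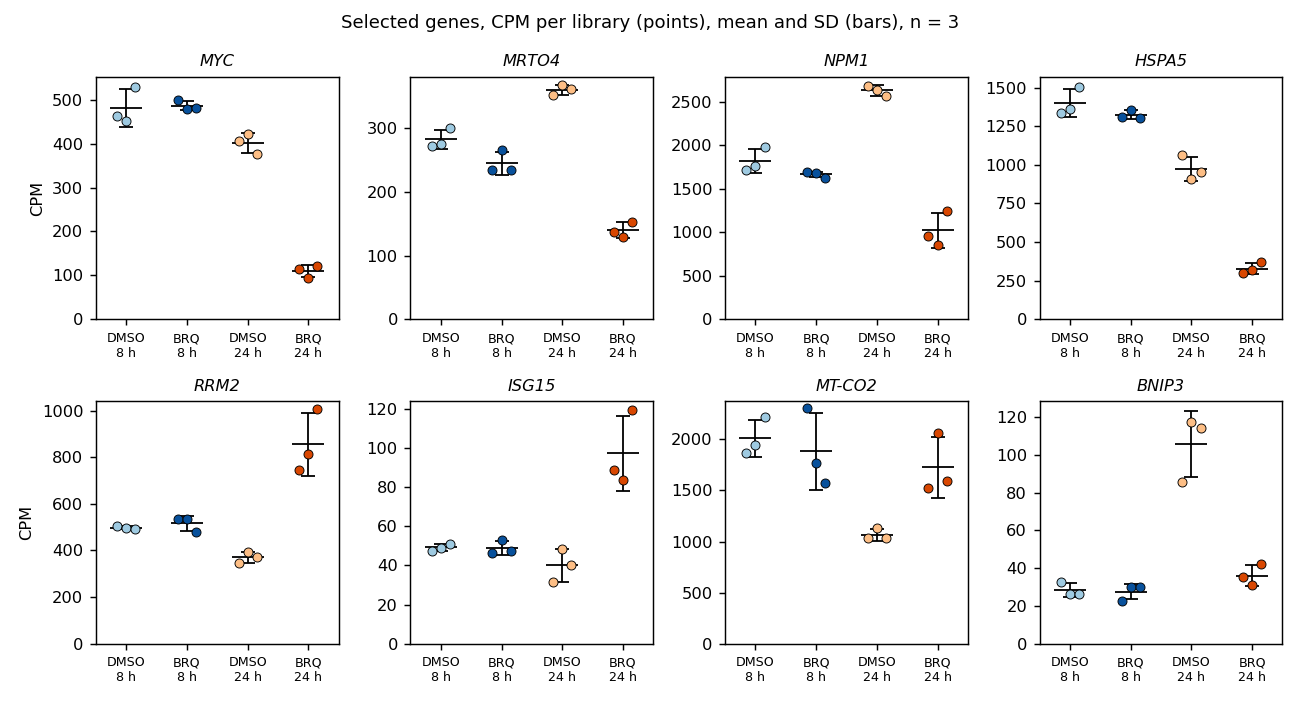
CPM (linear axes from 0) of 8 genes in each of the 12 libraries (points), with the group mean and SD (bars, n = 3). MYC averaged 401 CPM with DMSO and 110 CPM with BRQ at 24 h, and BNIP3 averaged 28.3 CPM with DMSO at 8 h, 106 CPM with DMSO at 24 h and 36.1 CPM with BRQ at 24 h.

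In all, 3680 of 11671 genes changed at 24 h: 1683 rose and 1997 fell, and 1192 of them (567 rises, 625 falls) differed by at least 2-fold. The groups' libraries did not overlap in 39.7% of genes, against 10% by chance. The biological coefficient of variation was 0.213 in the 24 h libraries alone, above the 0.16 of the fit of all 12. With library size as the only scaling the median of all genes was at 0.333, against 0.0436 with TMM, and 77.7% of 4931 calls were rises; changes here are relative to the TMM scale. The count was 2198 with only the 24 h libraries in the fit, and 4521, 2040 and 2235 with DMSO 24 h replicate 1, 2 or 3 as the only control.

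The largest changes were in genes of low abundance. BAIAP3, DIRAS1 and ALG1L had 0 counts in DMSO at 24 h and were at least 23.3-fold, 15.1-fold and 3.02-fold higher with BRQ. NUDT17 was 18.1-fold higher (interval 4.83 to 153), GPA33 17-fold (2.85 to 694) and PCSK4, a proprotein convertase, 14.4-fold (4.75 to 71.2). CDH24, a cadherin, rose by 3.58 ± 0.59, and TIAF1, whose reads may be shared with MYO18A, rose by 3.37 ± 0.78 on the log2 scale. ADM, the vasodilator peptide adrenomedullin, was lower with BRQ by 5.05 ± 0.75, at 0.343 ± 0.298 CPM, and PLOD2, a collagen lysyl hydroxylase, by 4.54 ± 0.96, at 1.61 ± 0.613 CPM. NEGR1 (-3.79 ± 0.78), the histone gene HIST3H2BB (-3.72 ± 0.53), CRIPAK (-3.50 ± 0.67), the WNT ligand WNT10A (-3.49 ± 0.59), the semaphorin receptor NRP2 (-3.44 ± 0.62) and USP41, a near copy of USP18 (-3.35 ± 0.89), also fell. Adjusted p-values of these 16 genes were at most 0.019. In DMSO at 8 h, ADM (0.204 CPM) and PLOD2 (0.716 CPM) lay below their level with BRQ at 24 h. ALG1L and GPA33 were at 2.16 and 4.69 CPM in DMSO at 8 h, above their 1.065 and 1.859 CPM with BRQ at 24 h. Their differences at 24 h therefore go with a change of the DMSO cells between the times. PCSK4, at 2.786 CPM in DMSO at 8 h, was higher with BRQ at 24 h (4.696 CPM). DMSO 24 h replicate 3, which held fibroblast markers at 1290 CPM, was the highest library for PLOD2 at 93 CPM, and without it PLOD2 was at -2.57, NRP2 at -2.50, ADM at -4.37 and CDH24 at 2.96, all still called, while GPA33 (10.8-fold, interval 1.8 to 439) and ALG1L (at least 1.91-fold) lost their calls. ALG1L, a copy of ALG1, also lost its call without BRQ 24 h replicate 3 (at least 2.02-fold). Without BRQ 24 h replicate 2, BAIAP3 was at least 14-fold higher, NUDT17 11.5-fold higher (interval 2.9 to 100) and USP41, then at 0 counts with BRQ, at least 9.36-fold lower. Without DMSO 24 h replicate 2, GPA33, then at 0 counts with DMSO, was at least 3.7-fold higher, PCSK4 28.1-fold (interval 4.91 to 1120) and TIAF1 17.9-fold (4.82 to 150). The calls of both these fits were kept. Bounds also drop with fewer counts behind the floor: without DMSO 24 h replicate 2 or 3, BAIAP3 was at least 15.2-fold or 14.7-fold and DIRAS1 at least 9.83-fold or 9.56-fold higher, both called, and ALG1L without replicate 2 was at least 1.97-fold higher.

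Camera called 18 of the 31 lists at 24 h, 10 up and 8 down. With an estimated correlation, ribosome biogenesis was the only call kept. Between BRQ at 8 h and BRQ at 24 h, 12 of the 18 lists were called in the same direction. With an estimated correlation that of ribosome biogenesis was kept (adjusted p = 0.0166), those of the DNA damage and TAL1 lists lay at the threshold (0.05 each), and the other 9 were lost. The lists of mitochondrial DNA and of cholesterol synthesis fell there, and those of purine synthesis (adjusted p = 0.497), glycolysis and hypoxia (0.469; median 0.192), dNTP and folate (0.0659) and apoptosis (0.0612) were not called. Counts of members are over all tested genes, and where a second count is missing it was the same adjusted over the list alone. No called list changed its direction relative to the median of all genes under any scaling; the median of the unfolded protein list alone among the called lists changed sign itself, to 0.0285 with library size only.

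Ribosome biogenesis fell as a list (27 of 39 fell, 12 were not called; median -0.54; adjusted p = 1.31e-13, and adjusted p = 0.00579 with an estimated correlation). NPM1, a nucleolar chaperone, fell by 1.36, the small nucleolar RNP protein NOP58 by 1.30 and the nucleolar helicase DDX21 by 1.11. Of 76 cytosolic ribosomal proteins 12 fell, 8 adjusted over the list alone, with RPL30 at -0.83 and RPL4 at -0.64, and the list was not called. MYC and its partners were not called as a list: 4 of 16 fell, among them MYC and LDHA, and MXD3, an antagonist of MYC, rose by 1.75. De novo purine synthesis was lower with BRQ than with DMSO (7 of 14 fell, 10 adjusted over the list alone; adjusted p = 0.0043, and adjusted p = 0.239 with an estimated correlation). ADSS was at -0.84 and the salvage enzyme HPRT1 at -0.88. Between BRQ at 8 h and BRQ at 24 h, 3 of the 14 rose and 4 fell, while in DMSO the list rose (median 0.303; adjusted p = 0.00272, and adjusted p = 0.419 with an estimated correlation). De novo pyrimidine synthesis had 6 tested genes, none of which passed the edgeR or camera test. Pyrimidine salvage was not called as a list and held 3 rises and 3 falls of 13, with the uridine kinases UCK1 at 0.69 and UCK2 at -0.64. UDP sugars and glycosylation held 5 rises of 20, with GNE at 0.86, and was not called as a list.

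The dNTP and folate list rose (6 of 12 rose, 1 fell; median 0.385; adjusted p = 0.0149, and adjusted p = 0.361 with an estimated correlation). RRM2 rose by 1.21, RRM2B by 0.87, SHMT1 by 0.68 and thymidylate synthase TYMS by 0.54, while the mitochondrial folate enzyme MTHFD1L fell by 0.82. DNA replication rose (22 of 42 rose and 5 fell, 23 and 7 adjusted over the list alone; adjusted p = 0.00396, and adjusted p = 0.107 with an estimated correlation). Cyclin E genes CCNE1 (0.96) and CCNE2 (1.17), E2F2 (1.07) and the flap endonuclease FEN1 (0.86) rose, while CHAF1A (-1.31), POLA1 (-0.87) and the helicase subunits MCM2 (-0.39) and MCM6 (-0.52) fell. DNA damage and replication stress rose (12 of 31 rose, 2 fell; adjusted p = 0.0168, and adjusted p = 0.107 with an estimated correlation), with the Fanconi genes FANCI and FANCD2 both at 0.70 and the kinases ATR at -0.64 and WEE1 at -0.43. The p53 target list rose (6 of 26 rose, 1 fell; adjusted p = 0.0392, and adjusted p = 0.164 with an estimated correlation). TP53I3 was at 2.14, TP53INP1 at 1.82 and FDXR at 1.47. Mitosis genes were not called as a list; 4 of 38 rose and 9 fell, 5 and 10 adjusted over the list alone, with AURKB at 0.69, PLK1 at -1.15 and HMMR at -1.27. Of 12 CDK inhibitors and G1 cyclins, also not called, 2 rose and 2 fell, with CDKN2C at 0.81 and CDK6 at -0.84. Replication-dependent histones fell as a list (2 of 6 fell; adjusted p = 0.0168, and adjusted p = 0.239 with an estimated correlation). HIST3H2A was at -1.86; 6 of the list's 55 genes were tested. The dNTP list lost its call without BRQ replicate 3 (adjusted p = 0.084), the p53 list without that library (0.0807) or DMSO replicate 1 (0.0577) or 2 (0.0623), and the histone list without DMSO replicate 3 (0.0832). Calls were also lost without the 2 libraries rich in fibroblast or epithelial markers for the dNTP and histone lists (adjusted p = 0.0912 and 0.087), and without the 3 libraries rich in NK cell markers for the p53 and DNA damage lists (0.0688 and 0.0688).

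Genes of the ATF4 stress response fell as a list (10 of 30 fell and 2 rose, 10 and 3 adjusted over the list alone; adjusted p = 0.0149, and adjusted p = 0.239 with an estimated correlation). ATF4 itself fell by 1.16, and the amino acid transporters SLC7A5 (-1.19) and SLC7A11 (-2.13) fell too. The unfolded protein list fell (5 of 17 fell; adjusted p = 0.0285, and adjusted p = 0.321 with an estimated correlation). HSP90B1 was at -1.71, and heat shock genes fell (6 of 10 fell; adjusted p = 0.0043, and adjusted p = 0.205 with an estimated correlation). HSPA8 was at -1.38. Glycolysis and hypoxia genes were lower with BRQ than with DMSO (17 of 28 fell, 2 rose; median -0.623; adjusted p = 2.28e-09, and adjusted p = 0.164 with an estimated correlation). HK2 (-1.63), PGK1 (-1.46), the oxygen-regulated mitophagy receptor BNIP3 (-1.56) and the growth factor VEGFA (-2.61) fell, while the enolase ENO2 rose by 1.07; without DMSO 24 h replicate 3 the median of the list was -0.44 and VEGFA was at -1.82. Genes of mitochondrial DNA were higher with BRQ than with DMSO (9 of 13, 12 adjusted over the list alone; median 0.701; adjusted p = 0.000807, and adjusted p = 0.328 with an estimated correlation). MT-CO2 was at 0.70 and MT-ND2 at 0.80; copies of these genes in the nuclear genome can share their reads. Between BRQ at 8 h and BRQ at 24 h the same list fell (5 of 13 fell; median -0.475; adjusted p = 0.0167, and adjusted p = 0.568 with an estimated correlation), by less than in DMSO, where its median was -1.12. Nuclear OXPHOS genes rose (7 of 34 rose, 3 fell; adjusted p = 0.0149, and adjusted p = 0.625 with an estimated correlation). CYC1 was at 0.63 and ATP5B at -0.49. Cholesterol synthesis was higher with BRQ than with DMSO (8 of 22 rose, 9 adjusted over the list alone, and 2 fell; adjusted p = 0.0392, and adjusted p = 0.321 with an estimated correlation). TM7SF2 was at 1.48, STARD4 at 0.87 and HMGCS1 at -0.69. Between BRQ at 8 h and BRQ at 24 h this list fell too (12 of 22 fell, 3 rose; median -0.528; adjusted p = 0.000108, and adjusted p = 0.0987 with an estimated correlation), against a median of -0.696 in DMSO. Of 17 ubiquinone-linked enzymes, not called as a list, 3 rose and 1 fell, with COQ4 at 0.89 and COQ3 at 1.00. Calls were lost without DMSO replicate 3 for the ATF4, unfolded protein and cholesterol lists (adjusted p = 0.0756, 0.0824 and 0.108), without BRQ replicate 1 or 2 for the unfolded protein list (0.063 and 0.0634), without BRQ replicate 3 for nuclear OXPHOS and cholesterol (0.361 and 0.0807), without DMSO replicate 1 for nuclear OXPHOS (0.109), and after GC correction for cholesterol (0.0526). Calls were also lost without the libraries rich in fibroblast or epithelial markers for nuclear OXPHOS and cholesterol (adjusted p = 0.219 and 0.19), and without those rich in NK cell markers for the unfolded protein list (0.0519).

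The TAL1 complex and its targets, a leukaemia programme, fell (10 of 18 fell, 11 adjusted over the list alone, and 1 rose; median -0.721; adjusted p = 9.45e-05, and adjusted p = 0.13 with an estimated correlation). MYB was at -0.74, RUNX1 at -0.77 and ALDH1A2 at -0.95. Interferon-stimulated genes rose (8 of 23; adjusted p = 0.00229, and adjusted p = 0.107 with an estimated correlation). ISG15 was at 1.27, STAT2 at 1.82 and IRF7 at 1.85. Autophagy and lysosome genes rose (7 of 16; adjusted p = 0.00178, and adjusted p = 0.107 with an estimated correlation). The sialidase NEU1 was at 1.92 and the lysosomal channel MCOLN1 at 1.40. Apoptosis genes rose as a list (5 of 26 rose and 2 fell, 2 and 1 adjusted over the list alone; adjusted p = 0.0457, and adjusted p = 0.164 with an estimated correlation). BAX was at 0.89 and BCL2L1 at -0.67. Lists of T-cell receptor signalling (5 rises and 5 falls of 22), thymocyte stage (1 and 7 of 19), Notch targets (2 and 6 of 12, 2 and 7 adjusted over the list alone), immediate early genes (3 falls of 16) and transcription elongation (3 and 3 of 14, 3 and 4 adjusted over the list alone) were not called; in them FYN was at -0.76, LEF1 at -0.92, NRARP at -1.84, EGR1 at -1.69 and HEXIM1, an inhibitor of P-TEFb, at 1.12. The apoptosis list lost its call without DMSO replicate 1 (adjusted p = 0.0764) or 2 (0.0536) or BRQ replicate 2 (0.068) or 3 (0.0844) of 24 h, and without the libraries rich in fibroblast or epithelial markers (0.068) or in NK cell markers (0.0709).

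**Figure D3:**
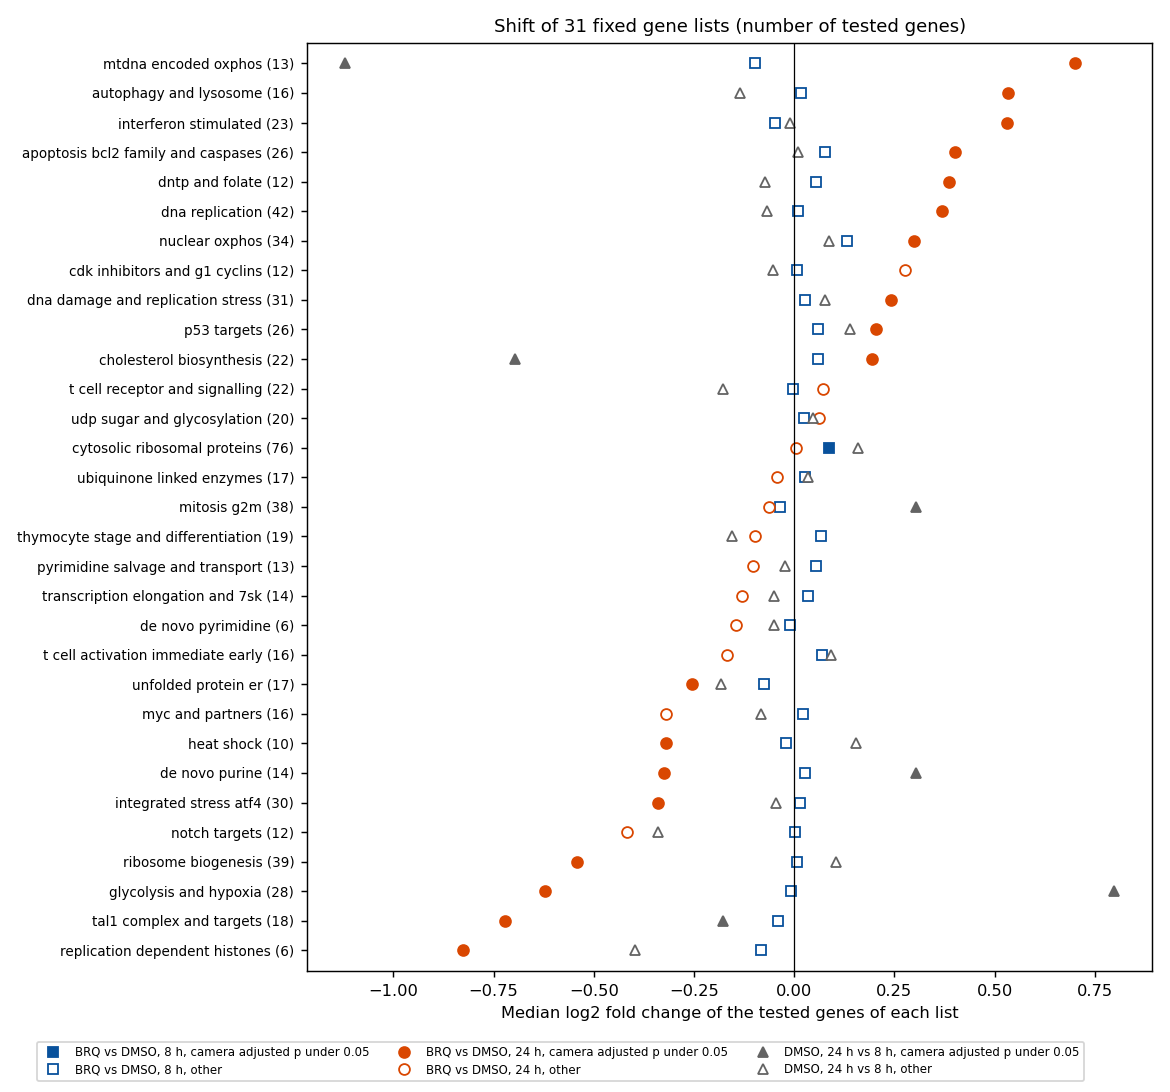
Median log2 fold change of the tested genes of each of 31 lists (number of tested genes in brackets) for BRQ against DMSO at 8 h and at 24 h and for DMSO at 24 h against 8 h. Filled symbols mark a camera adjusted p under 0.05; at 24 h these medians run from -0.826 for histones to 0.701 for genes of mitochondrial DNA.

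The interaction term tests whether the effect of BRQ at 24 h differed from that at 8 h. MYC differed most clearly among the genes always reported: its effect was lower at 24 h by -1.88 ± 0.16 on the log2 scale (adjusted p = 1.6e-06). Ribosome biogenesis was lower at 24 h as a list (19 of 39 genes lower, 24 adjusted over the list alone; median -0.533; adjusted p = 4.98e-15, and adjusted p = 0.00386 with an estimated correlation). NPM1 was at -1.24 and DDX21 at -1.11. Glycolysis and hypoxia genes were lower (11 of 28, and 13 lower with 1 higher adjusted over the list alone; median -0.659; adjusted p = 3.88e-09, and adjusted p = 0.164 with an estimated correlation). PGK1 was at -1.51 and HK2 at -1.78. Genes of mitochondrial DNA were higher (4 of 13, 9 adjusted over the list alone; median 0.729; adjusted p = 1.94e-05, and adjusted p = 0.237 with an estimated correlation). In all, 1056 genes differed, 313 higher and 743 lower, and 15 lists, 6 higher and 9 lower. Among the largest differences, CDH24 (3.34 ± 0.77) was at 0.713 ± 0.624 CPM in DMSO and 8.47 ± 2.33 CPM in BRQ at 24 h, against 4.34 ± 1.64 and 5.14 ± 0.186 CPM at 8 h. NRP2 (-4.25 ± 0.86) was at 10.1 ± 8.64 and 0.925 ± 0.388 CPM at 24 h, against 2.91 ± 1.36 and 5.11 ± 0.762 CPM at 8 h, and without DMSO 24 h replicate 3 its difference was -3.30 and that of CDH24 was 2.73. With library size only, the median of all genes was 0.262 and 73.4% of 1455 calls were higher. The count fell to between 575 and 672 without any of the 6 libraries of 8 h or BRQ 24 h replicate 1 or 2 (575 without BRQ 8 h replicate 2, 604 without BRQ 8 h replicate 1, 605 without BRQ 8 h replicate 3, 631, 672 and 652 without DMSO 8 h replicates 1, 2 and 3, 655 and 668 without BRQ 24 h replicates 1 and 2), and was 399 without the 3 libraries rich in NK cell markers.

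The comparison of DMSO at 24 h with DMSO at 8 h gives the change of vehicle-treated cells between the times. Its log2 fold changes correlated with transcript GC content across genes (Spearman -0.399), against 0.135 for BRQ at 8 h and 0.181 for BRQ at 24 h. The list calls of this comparison were not tested again after GC correction or on leaving out a library. All 13 genes of mitochondrial DNA fell (median -1.12, camera adjusted p = 5.53e-22, and adjusted p = 0.0627 with an estimated correlation), with MT-CO2 going from 2008 ± 186 to 1065 ± 55.6 CPM (n = 3). All genes whose symbol starts with MT- together took 0.705% to 0.732% of the counts in DMSO at 24 h. In DMSO at 8 h they took 1.44% to 1.63%. Glycolysis and hypoxia genes rose (20 of 28, 21 adjusted over the list alone; median 0.798; adjusted p = 3.01e-22, and adjusted p = 0.0627 with an estimated correlation). BNIP3 was at 1.90 ± 0.18, PDK1 at 1.44 ± 0.17 and LDHA at 1.09 ± 0.13. Cholesterol synthesis fell (14 of 22 fell, 1 rose; median -0.696; adjusted p = 3.67e-14, and adjusted p = 0.0418 with an estimated correlation). Mitosis genes rose (10 of 38, with 13 rises and 2 falls adjusted over the list alone; median 0.303; adjusted p = 6.88e-06, and adjusted p = 0.0627 with an estimated correlation). BUB1 was at 0.74. De novo purine synthesis rose (6 of 14; adjusted p = 0.00272, and adjusted p = 0.419 with an estimated correlation) and the TAL1 list fell (6 of 18 fell, 8 adjusted over the list alone, and 1 rose; adjusted p = 0.0113, and adjusted p = 0.419 with an estimated correlation). ASNS, the asparagine synthetase in the ATF4 list, fell by 2.19, and MYC was not called (-0.26 ± 0.11, adjusted p = 0.14).

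Of single genes, 1371 changed in DMSO between the times, 681 up and 690 down; 29.9% of genes had no overlap between the groups' libraries, against 10% by chance. ADM was 63-fold higher at 24 h (interval 17.1 to 527), PPFIA4 rose by 3.25 ± 0.72 to 6.17 ± 0.871 CPM, and FILIP1L rose by 3.05 ± 0.57. PLOD2 (5.66 ± 1.17), the kinase SGK1 (2.65 ± 0.67) and the myosin MYO1E (2.44 ± 0.63) rose too. ALG1L had 0 counts at 24 h and was at least 6.44-fold lower, GPA33 was 41.4-fold lower (interval 7.06 to 1670) and PCSK4 8.28-fold lower (2.55 to 42.7); PPP1R3D (-2.89 ± 0.75), UBXN10 (-2.87 ± 0.63) and FAM53A (-2.87 ± 0.89) fell. Without DMSO 24 h replicate 3, ALG1L was at least 4.1-fold lower, GPA33 26.3-fold lower (interval 4.49 to 1060), ADM 37.6-fold higher (9.8 to 320), PLOD2 was at 3.69 and FAM53A, then at 0 counts at 24 h, was at least 8-fold lower, and SGK1 (1.20) and PCSK4 (7.9-fold lower, 1.99 to 68.6) were not called. Without DMSO 24 h replicate 2, ALG1L was at least 4.22-fold lower, GPA33, then at 0 counts at 24 h, was at least 9.04-fold lower, PCSK4 16.3-fold (interval 2.68 to 666), PPP1R3D 12.7-fold (3.29 to 108) and UBXN10 17.2-fold (4.54 to 145), and FAM53A (-2.30) was not called. Without DMSO 24 h replicate 1, MYO1E (1.63), PCSK4 (5.86-fold lower, interval 1.8 to 30.2) and FAM53A (-2.38) were not called. Without DMSO 8 h replicate 1, PLOD2 was 129-fold higher (interval 35.5 to 1070), and SGK1 (2.22), MYO1E (2.61), PCSK4 (7.44-fold lower, 2.13 to 39.8), PPP1R3D (-2.74) and FAM53A (-2.71) were not called. Without DMSO 8 h replicate 2, PPFIA4 was 19.9-fold higher (interval 5.25 to 168), and PLOD2 (5.31), SGK1 (2.69), MYO1E (2.36) and PPP1R3D (-2.73) were not called. Without DMSO 8 h replicate 3, GPA33 was 27.3-fold lower (interval 4.36 to 1130), and PLOD2 (5.33), MYO1E (2.38) and FAM53A (-2.54) were not called. FAM53A was also not called without BRQ 8 h replicate 1 (-2.87), 2 (-2.87) or 3 (-2.87) or BRQ 24 h replicate 1 (-2.87). With library size only, the median of all genes was -0.111 and 25.7% of calls were rises. The count was 511 with only the DMSO libraries in the fit, 897 after GC correction, and 521, 737 and 736 without DMSO 8 h replicate 1, 2 or 3.

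The effects at 8 h and at 24 h share no library, so their calls can be set side by side. In the main fit they do share the estimate of each gene's spread. The expected overlaps below take every gene as equally likely to be called, so they are no strict level of chance. Of the 4 genes that fell at 8 h, EIF4A2 (-1.61), MARCKS (-0.91) and EXT1 (-0.43) fell at 24 h as well, against 0.684 expected from independent lists, and INTS6 was not called at 24 h (-0.15, adjusted p = 0.409). None of the 4 rose by edgeR. Across genes, which are not independent replicates, the log2 fold changes at the 2 times had a Pearson correlation of 0.211 and a Spearman correlation of 0.261. With only the compared groups in each fit, 150 calls were shared in direction, 146 falls and 4 rises, against 19.9 and 0.462 expected, and 1 gene went opposite ways.

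Single libraries stood apart. DMSO 24 h replicate 1 deviated most from its group (SD of 0.526 on the log2 scale over genes, against 0.225 to 0.402 in the other libraries). Its deviations from the mean of the 12 libraries correlated with transcript GC content across genes (Spearman -0.447), and it had the fewest genes with a count, 13677. The correlation with GC was also below 0 in DMSO 24 h replicates 2 (-0.0914) and 3 (-0.204). It ran from 0.0522 to 0.36 in the libraries of 8 h and from -0.101 to 0.0422 in BRQ at 24 h. DMSO 24 h replicate 3 held 1290 CPM summed over 8 fibroblast markers, against 1.48 to 4.8 CPM in the other 11 libraries, and FN1, a fibroblast matrix gene, was at 910 CPM in it. Epithelial markers summed to 100 CPM in DMSO 24 h replicate 3 and 182 CPM in BRQ 24 h replicate 3. BRQ 24 h replicate 3 also had a low voom sample weight, 0.27, against 0.234 in DMSO 24 h replicate 1 and at least 0.909 in the others. Its deviations had the strongest correlation with transcript length of all libraries (Spearman -0.279). NK cell markers summed to 102 CPM in BRQ 8 h replicate 1, 82.1 CPM in DMSO 24 h replicate 2 and 289 CPM in BRQ 24 h replicate 2. B-cell markers lay between 45.6 and 78.2 CPM in all 12 libraries, and erythroid, megakaryocyte and myeloid markers reached at most 8.87, 2.88 and 30.4 CPM, with no library over 10 times the median of the 12. CDKN1A, the p21 inhibitor, had too few counts to be tested: it was at 1.63, 2.88 and 0.8 CPM with BRQ at 24 h and at 1.16, 2.27 and 25.8 CPM with DMSO, the last in the library with fibroblast markers.

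**Figure D4:**
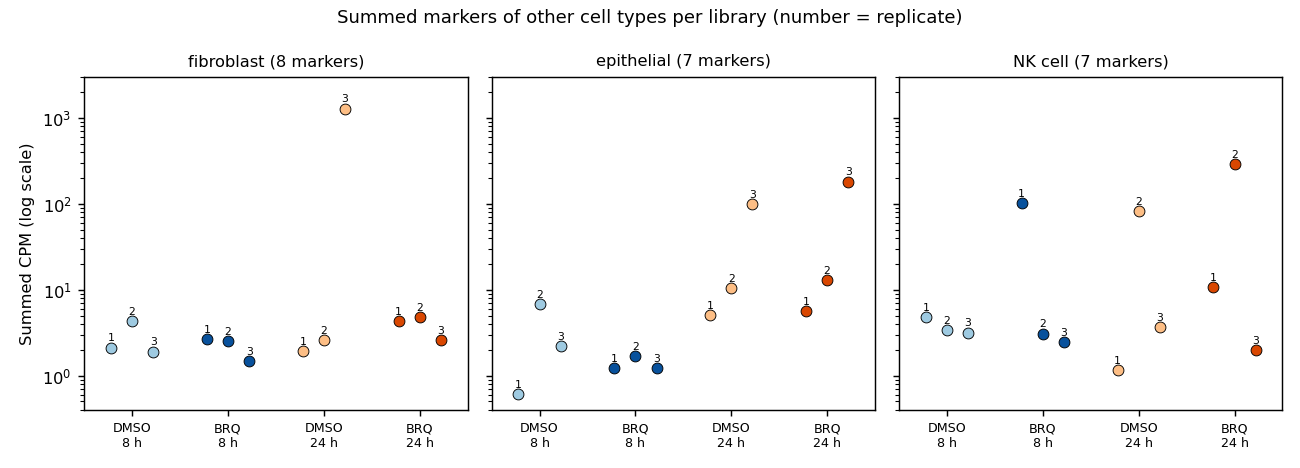
Summed CPM (log axis) of 8 fibroblast, 7 epithelial and 7 NK cell markers in each of the 12 libraries, numbered by replicate. DMSO 24 h replicate 3 reached 1290 CPM for fibroblast markers, BRQ 24 h replicate 3 reached 182 CPM for epithelial markers and BRQ 24 h replicate 2 reached 289 CPM for NK cell markers.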

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

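Of the tests in this part, those of the hypoxia list against the change of the DMSO cultures, of both lists against GC content and against DMSO 24 h replicate 3, and of the other-cell markers were chosen after the results were seen.

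The interaction term of the edgeR model picked out results in which the effect of BRQ differed between 24 h and 8 h: 1056 genes and 15 lists. The genes with the largest differences were DIRAS1 (10.2, a fitted value that is no bound, since 2 groups had 0 counts), NUDT17 (5.08), GPA33 (4.69), CDH24 (3.34), PPP1R3D (3.15), PCSK4 (3.08), MME (-4.84), TTC23 (-4.62), NRP2 (-4.25), USP41 (-4.01), NEGR1 (-3.69) and CRIPAK (-3.60), and MYC was at -1.88. All but CDH24, NRP2, CRIPAK and MYC lost their call on leaving out at least 1 library, and MME was at -2.75 without DMSO 24 h replicate 3. The differences of NUDT17, GPA33 and PCSK4 are fitted values as well. These genes had 2, 1 and 3 counts in DMSO at 24 h, and no interval was computed for their differences. Lists with a lower effect at 24 h were ribosome biogenesis (median -0.533), glycolysis and hypoxia (-0.659), TAL1 targets (-0.529), purine synthesis (-0.376), heat shock (-0.332), MYC partners (-0.255), ATF4 response (-0.241), unfolded protein (-0.172) and histones (-0.877). Lists with a higher effect were genes of mitochondrial DNA (0.729), autophagy and lysosome (0.633), interferon-stimulated genes (0.409), DNA replication (0.355), dNTP and folate (0.29) and DNA damage (0.206). Of these, only the ribosome biogenesis call held with an estimated correlation (adjusted p = 0.00386); adjusted p-values of the others ran from 0.112 to 0.435. With library size as the only scaling the ATF4 and unfolded protein medians changed sign (0.000518 and 0.0707), against a median of 0.262 for all genes.

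The lower level of glycolysis and hypoxia genes in BRQ at 24 h (median -0.623) and that of ribosome biogenesis genes (-0.542) may have different sources. The GC trend of the libraries is argued against for both, since after GC correction the medians were -0.647 and -0.609 and both lists were still called. Between BRQ at 24 h and BRQ at 8 h, ribosome biogenesis fell (median -0.549), which argues against the change of the DMSO cultures as its source, and without DMSO 24 h replicate 3 its median was -0.597, which argues against RNA of other cells in that library. For glycolysis and hypoxia the same comparison of BRQ libraries gave a median of 0.192 and no call, so that a candidate explanation is a rise in the DMSO cultures by 24 h that the BRQ cultures did not show. Whether RNA of other cells in DMSO 24 h replicate 3 adds to it cannot be told apart: without that library the list was still called with a median of -0.44.

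Markers of other cell types stood out in single libraries. A response to BRQ or to time shared by the libraries of a group is argued against, since in no group did more than 1 of the 3 libraries hold markers of a type at over 10 times the median library. This count restates the observation itself and is no separate test. RNA or reads from other cells is a candidate source: 7 of the 8 fibroblast markers were higher in DMSO 24 h replicate 3 than in each of the other 11 libraries. That library was picked by the sum of the same markers, so this count is not independent of the choice. A set of 236 genes particular to it, led by FN1 (910 CPM), took 1.05% of its counts. In BRQ 24 h replicate 2 such genes took 0.1% of counts, with GNLY at 203 CPM, and in BRQ 24 h replicate 3 they took 0.0732%, with KRT19 at 72.5 CPM. Of the 236 genes, 24 were tested and 2 were called at 24 h.

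The splits of the 6 libraries of a comparison are 10 in all, the real one included, too few for a share under 0.05. The real split gave 4 genes at 8 h, 3680 at 24 h and 1371 for DMSO over time, each in 1 of 10 splits, and the highest other count by edgeR was 0 in each. For lists, 8 of 10 splits gave at least the 1 list called at 8 h, with up to 5, and 1 of 10 gave the 18 lists of 24 h, with 12 as the highest other. For the difference between times, 10 of 100 drawn splits gave at least 1056 genes (highest other 2244) and 10 of 100 gave at least 15 lists (highest other 19). The other 9 such splits all kept the 24 h groups and with them the effect at 24 h, while splits that parted the 24 h groups gave 0 genes by edgeR. This count therefore does not test chance for the difference. For the overlap of calls, 1 of 100 splits gave the 3 shared genes and the highest other was 0. The other splits of 8 h or of 24 h called 0 genes by edgeR, which left their overlap at 0, so this count does not exclude chance.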

How the results depend on the processing

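Alternatives named here as added (GC correction, sample weights, left-out groups of libraries, single controls) were chosen after seeing the data; the others were planned before the data were examined. Over all alternatives, the values of named genes kept direction and side of the threshold in 3680 cases, lost the call in 312, gained it in 7 and changed sign in 33; called lists kept their call in 517 cases and lost it in 93. Every change of sign was in a gene that was not called. The cause of a change was not tested unless given.

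For BRQ against DMSO at 8 h (4 genes), 37 genes were called with DESeq2, 37 without a low-count filter, 2 with limma-trend on log2(TPM+1), 185 with only the groups compared (biological coefficient of variation 0.089 against 0.16), 0 with an absolute log2 fold change of at least 1 by edgeR (467 at an unadjusted p under 0.05), 149 with voom sample weights, 70 without the 3 DMSO 24 h libraries and 183 with the 8 h libraries only and GC correction. Leaving out 1 library gave 0 to 77. At 24 h (3680 genes), 2189 were called at an adjusted p under 0.01, 1192 with the fold-change minimum, 2198 with only the groups compared, and 4521, 2040 and 2235 with DMSO 24 h library 1, 2 or 3 as the only control. A control of 1 library has no spread of its own, so that these fits take it from the other groups; 1109 genes (279 rises, 830 falls) were called in all 3. Leaving out 1 library gave 2944 to 3637. For the difference (1056), 404 were called at an adjusted p under 0.01, 495 with the fold-change minimum, 2024 with sample weights and 399 without the libraries rich in NK cell markers, and 575 to 1356 on leaving out 1 library. For DMSO over time (1371), 430 were called at an adjusted p under 0.01, 291 with the fold-change minimum, 511 with only the groups compared and 897 after GC correction, and 521 to 1788 on leaving out 1 library. The overlap of calls (3) was 0 with the fold-change minimum and 150 with only the groups compared, which was added. Fewer libraries in a fit leave it fewer degrees of freedom, and a stricter threshold leaves fewer calls by construction. The spread also differed between the times: the biological coefficient of variation was 0.089 in the 8 h libraries alone and 0.213 in those of 24 h. The value of 0.16 shared by all 12 libraries lies between them. The counts of 4 and 3680 are therefore not a like-for-like comparison of the times.

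Scaling by library size only gave 77.7% rises at 24 h against 45.7%, 73.4% against 29.6% for the difference and 25.7% against 49.7% for DMSO over time; limma-trend on log2(TPM+1), which has no composition correction, gave 77.9%, 71.8% and 22.4%. The filter on a CPM of at least 1 in 3 libraries, planned as the stricter, tested 13855 genes.

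Of the gene lists, camera with an estimated correlation called 0 of 1 list at 8 h, 1 of 18 at 24 h and 1 of 15 for the difference. At 8 h, fry called 0 lists and the GC correction left 0, and leaving out 1 library gave 0 to 4. At 24 h and for the difference, leaving out 1 library gave 14 to 18 and 10 to 17 lists, and fry, which tests a list without the other genes as a background, called 24 and 17. At 24 h these included 7 lists that camera did not call: MYC partners (adjusted p = 0.000404), Notch targets (0.000729), UDP sugars (0.00219), thymocyte stage (0.00219), mitosis (0.00554), de novo pyrimidine synthesis (0.0126) and CDK inhibitors (0.0356). It did not call nuclear OXPHOS at 24 h (0.164), nor mitochondrial DNA (0.0562) and dNTP and folate (0.0859) for the difference.

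The replicate number as a block gave 4 genes at 8 h, 3796 at 24 h, 1159 for the difference and 1468 for DMSO over time, an overlap of 3, and 2, 18 and 15 lists; of single calls it ended that of HES4 at 24 h (1.59). The numbers do not pair the samples: same-numbered libraries had correlations of deviations between -0.117 and 0.11, 1 of 18 pairs was over 0.1, and 4 of 12 libraries correlated best with their own number.

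Signs that changed, all on the log2 scale and in genes that were not called: CAD at 8 h (0.0025) was at -0.0026 with upper quartile scaling, -0.0022 with the CPM filter, -0.0011 with only the groups compared, -0.0443 after GC correction, -0.0148 with sample weights, -0.0080 without the 3 DMSO 24 h libraries and -0.0387 with the 8 h libraries only and GC correction, and ran from -0.075 to 0.0627 on leaving out 1 library, with 9 of 12 values below 0. MYC at 8 h was at -0.0126 after GC correction, -0.0088 with the 8 h libraries only and GC correction, and from -0.0285 to 0.091 on leaving out 1 library, with 3 of 12 values below 0. At 24 h, library size only and limma-trend gave 0.0175 and 0.0056 for DHODH, 0.123 and 0.105 for UMPS and 0.122 and 0.0982 for CAD, which was at 0.0587 with DMSO 24 h library 3 as the only control. For the difference they gave 0.0546 and 0.0419 for DHODH and 0.0795 and 0.0535 for CAD, and DHODH was at 0.0702 without the libraries rich in fibroblast or epithelial markers.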

Other observations

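Of the tests in this part, those on GC content and on the further matching of gene span were chosen after the results were seen, as was the list of 39 splicing regulators, which was drawn up from the genes called at 8 h; genes named here outside the fixed rule were chosen after their values were seen.

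In the fit of the 8 h libraries alone, 179 genes fell and 6 rose with BRQ. The falls include pseudogenes such as SERBP1P1, HNRNPA1P48 and NPM1P27, whose reads may be shared with near-copy genes, so not all falls need be separate. The lowest adjusted p-values were those of EIF4A2, INTS6 and MARCKS. Of the others that fell, the spliceosome helicase DHX15 fell by 0.59 ± 0.06 on the log2 scale (1391 to 929 CPM), the splicing factor RBM39 by 0.64 ± 0.07 (496 to 319 CPM), SYNCRIP by 0.54 ± 0.06 (2191 to 1508 CPM), the calcineurin subunit PPP3CB by 0.63 ± 0.08 (458 to 296 CPM), HNRNPD by 0.50 ± 0.06 (2551 to 1808 CPM) and the U2 snRNP subunit SF3B1 by 0.51 ± 0.07 (1462 to 1033 CPM). Their adjusted p-values (edgeR, Benjamini-Hochberg) were at most 2.98e-06. The 6 rises were CCNE2, encoding a cyclin E (0.64 ± 0.16), the Fanconi anaemia gene FANCG (0.63 ± 0.16), HEXIM1, an inhibitor of the elongation factor P-TEFb (0.43 ± 0.10), the antiproliferative gene TOB1 (0.76 ± 0.17), the splicing kinase CLK3 (0.52 ± 0.09) and SNAPC4 (0.77 ± 0.21), with adjusted p-values between 0.000363 and 0.0496.

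At 24 h the 39 splicing regulators of the SR and hnRNP families were lower with BRQ: 30 of 38 tested genes fell, with SRSF2 at -1.55, SRSF1 at -1.19 and HNRNPA3 at -1.19. The list's median was -0.677 (camera p = 6.25e-23, and p = 0.00391 with an estimated correlation). Genes that fell at 8 h often fell at 24 h too, so these p-values are not fully independent of how the list was made. In DMSO between 8 h and 24 h, 8 of the list's genes rose and 2 fell (median 0.154, camera p = 0.0179, and p = 0.357 with an estimated correlation). Between BRQ at 8 h and BRQ at 24 h, 3 of the list's genes rose and 23 fell (median -0.492). At 8 h the list's median was -0.107 in the fit of all 12 libraries, where each of the 38 was short of the threshold. In the fit of the 8 h libraries alone 7 of the 38 fell and 31 were not called, counts that are not independent of how the list was made.

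The excess of falls in the fit of the 8 h libraries alone was set against 2 technical explanations. After GC correction 175 genes fell and 8 rose, which argues against the GC trend of the libraries, although the fallen genes had a median transcript GC of 42.2% against 47.9% for tested genes. With all 6 libraries thinned to 3239844 counts, at least 169 genes fell over 5 draws, which argues against the deeper sequencing of BRQ. A candidate explanation is a preferential fall of transcripts of long genes. The fallen genes had a median span of 59.6 kb against 32.1 kb in lists matched on expression, at percentile 100 of 10000 lists. When exon length and GC were matched as well, they lay at percentile 99.99 (43.7 kb). The span of the genes that fell at 24 h was not tested, so whether long genes fall earlier than others is open. No test here tells slower transcription of long genes from faster loss of their transcripts.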
